A study of Mus musculus with 6 samples.

How the data were processed

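Gene expression was measured by RNA sequencing in fetal liver cells of mouse embryos at embryonic day 14.5, described in the labels as haematopoietic stem and progenitor cells. There were 6 samples, 3 with an intact Prl2 gene (Prl2+/+) and 3 lacking it (Prl2-/-). PRL2 is a small protein tyrosine phosphatase, and the gene that encodes it is listed as Ptp4a2. Per the labels' protocols, total RNA was purified on columns, full-length cDNA was made from a very small input with a template-switching kit, and libraries were made by transposon tagmentation, a method that does not mark the strand of the transcript.

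The authors' deposited table holds raw counts per gene, per the file header, and the values are whole numbers. Reads were aligned with STAR and counted per gene with featureCounts, per the submitters' processing notes; their versions, the handling of reads that map to several places and the genome build are not given in the sources used here. The table carries the exon positions of each gene. Of 12135 symbols shared with GENCODE M21, an annotation of the mouse genome build GRCm38, 12126 overlapped the annotated position and 9037 had a gene end within 5 bp of it, so positions are given on GRCm38. The table held 12579 genes. Every gene had a CPM (counts scaled to a common library total) of at least 0.2 in at least 3 libraries, so genes of low abundance had been left out before deposit. Genes absent from the table, among them Ddx3y, Eif2s3y, Kdm5d and Uty, the Y-linked genes chosen as a check of the samples, and the mitochondrially encoded genes, were not analysed here. The adult globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were absent too. Reads shared between near-identical copies, such as processed pseudogenes, and reads of overlapping genes on opposite strands could not be separated, so the counts of such genes are uncertain.

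Total counts were 26141378, 33613949 and 25965111 in Prl2+/+ replicates 1 to 3 and 35802952, 29525301 and 37026282 in Prl2-/- replicates 1 to 3. No pair of libraries had identical counts or agreed within sampling noise, as the chi-square per gene was at least 19.8 for every pair.

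Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 12576, scaled with TMM factors (0.991 to 1.01) and tested with the quasi-likelihood F test of Prl2-/- against Prl2+/+ over all 6 libraries, with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are Prl2-/- minus Prl2+/+. Standard errors (SE) were taken as the fold change divided by the square root of F, and 95% confidence intervals from the t distribution with the test's degrees of freedom. The common biological coefficient of variation was 0.264. The edgeR workflow was tested on simulated counts for 12548 genes with the means and library sizes of this comparison. It recovered 26% of 50 genes changed 1.5-fold, 68% of 50 changed 2-fold, 94% of 50 changed 4-fold and 100% of 50 changed 8-fold, with 12 false calls in all. The changed genes were drawn only from genes with a mean CPM of at least 4, so these rates do not cover genes of lower abundance.

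Gene lists for the signalling pathways, cell types and cell states of the fetal liver were tested with camera in limma 3.58.1, with its preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2. Of 41 lists with a measured member, 39 were tested and their p-values adjusted over the 39. The embryonic globins had fewer than 3 measured members, and the sex-linked genes served as a check of the samples. A further list, of mitochondrially encoded proteins, had no measured member. The tests were repeated with an estimated correlation and with fry, and the members were also adjusted over the list alone. The clustering of called genes around Ptp4a2 was tested with a two-sided Fisher's exact test within 10 Mb. List means were compared between genotypes with two-sided exact permutation tests, which cannot give a p under 0.1 with 3 against 3.

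The genes named are Ptp4a2, Ptp4a1, Ptp4a3, Flt3, Kit and Cbl; the 10 largest changes in each direction among protein-coding genes past the threshold with a mean log2 CPM of at least 2 and no overlap between genotypes; up to 4 called members of each list, or the member with the smallest p where the list was called but no member was; and, since fewer than 10 genes were called, the 10 genes with the smallest p. Some items that the rule names are not reported here. Other genes are named as examples from the lists or, where stated, because of their values. Groups, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives covered scaling, filters, DESeq2 1.42.0, limma-voom, the likelihood ratio test, robust estimation and the replicate number as a block. They also covered haemoglobin and ribosomal protein genes left out, sex-linked genes left out and each library left out. A planned covariate from those Y-linked genes was not run.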

Results

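RNA was sequenced from E14.5 fetal liver cells of 3 Prl2+/+ and 3 Prl2-/- samples, described in the labels as haematopoietic stem and progenitor cells. The question was how loss of the phosphatase PRL2 alters transcription, in particular transcription that depends on FLT3. FLT3 is a receptor tyrosine kinase of early haematopoietic progenitors. Libraries held 26141378, 33613949 and 25965111 counts in Prl2+/+ replicates 1 to 3 and 35802952, 29525301 and 37026282 in Prl2-/- replicates 1 to 3. Among the genes analysed, Mpo, which encodes myeloperoxidase of granulocyte precursors, had the most counts in every library, at 0.988% to 1.37% of counts. The adult globin genes and the mitochondrially encoded genes were not among those analysed, so Mpo could not be ranked against them. The labels do not state that each library came from a separate embryo, so p-values measure the spread between these samples, which may be partly technical.

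Ptp4a2, the gene that encodes PRL2, was nearly absent from the Prl2-/- cells. It lies on chromosome 4 (129820479 to 129850003, plus strand). It had 8088, 9906 and 8135 counts in the Prl2+/+ libraries and 44, 38 and 38 in the Prl2-/- libraries, or 306 ± 8.51 CPM against 1.18 ± 0.132 CPM (SD, n = 3 each). Its log2 fold change was -8.02 ± 0.098 (SE), with an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 3.31e-07. All 6 libraries therefore matched their genotype labels. The other members of the family did not pass the test: the log2 fold change was 0.042 ± 0.154 (SE) for Ptp4a1 and 0.16 ± 0.132 for Ptp4a3, with edgeR adjusted p of 0.962 and 0.899.

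Besides Ptp4a2, 4 genes changed. Hmgn2, a nucleosome-binding protein, and Stmn1, the microtubule-destabilising protein stathmin, fell in the Prl2-/- cells; Fuca1, a lysosomal fucosidase, and Ncmap, a membrane protein of myelinating Schwann cells, rose. Hmgn2 had 1215 ± 81.0 CPM in Prl2+/+ and 406 ± 33.5 CPM in Prl2-/- (SD, n = 3 each), a log2 fold change of -1.58 ± 0.083 (SE; edgeR adjusted p = 0.00186). Stmn1 went from 316 ± 13.7 to 142 ± 4.81 CPM, a log2 fold change of -1.15 ± 0.057 (edgeR adjusted p = 0.00186). Fuca1 went from 107 ± 2.55 to 169 ± 3.14 CPM, a log2 fold change of 0.65 ± 0.051 (edgeR adjusted p = 0.0143). Ncmap had 4, 6 and 7 counts in the Prl2+/+ libraries and 211, 125 and 223 in the Prl2-/- libraries, a log2 fold change of 4.72 ± 0.335 (edgeR adjusted p = 0.00992). Thus 5 of 12576 genes passed the threshold, 2 higher and 3 lower in Prl2-/-, and for each of them all 3 Prl2-/- libraries lay on one side of all 3 Prl2+/+ libraries. Hmgn2 and Stmn1 have processed copies elsewhere in the genome, and their counts are uncertain to that extent. The count was 36 with DESeq2 and 21 with the edgeR likelihood ratio test. Fuca1 lost its call without any 1 of the 6 libraries (edgeR adjusted p 0.0699 to 0.194), and Ncmap lost it without Prl2+/+ replicate 1, Prl2+/+ replicate 2, Prl2-/- replicate 1 or Prl2-/- replicate 3 (up to 0.136), so that the count was 3 without any of those 4 libraries.

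**Figure D1:**
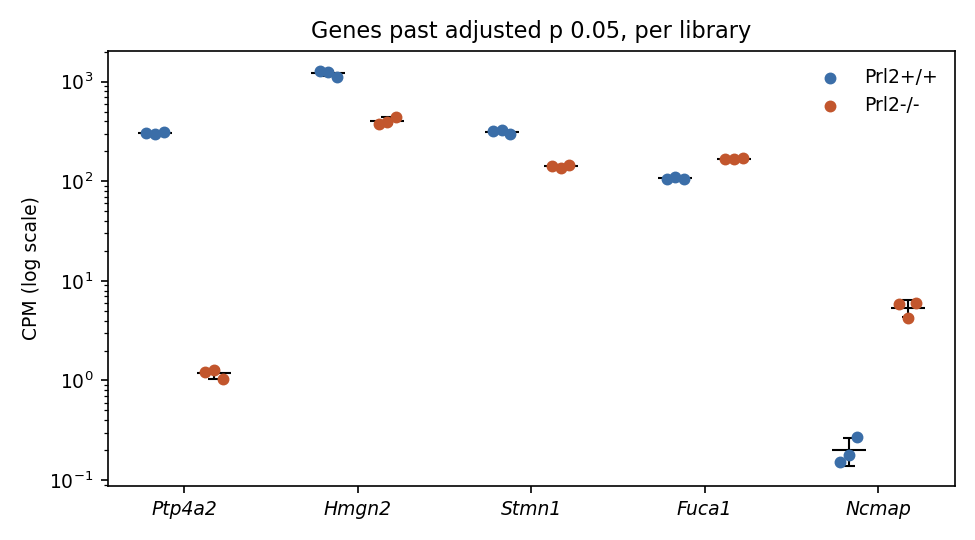
CPM on a log axis of the 5 genes past an edgeR adjusted p of 0.05, one point per library (blue Prl2+/+, orange Prl2-/-), with the mean and SD of 3 libraries in black. Ptp4a2 went from 306 to 1.18 CPM, Hmgn2 and Stmn1 were lower and Fuca1 and Ncmap higher in all 3 Prl2-/- libraries.

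The 5 called genes shared 1 stretch of chromosome 4. Hmgn2 (133964739 to 133967991), Stmn1 (134468320 to 134473843), Ncmap (135369577 to 135398227) and Fuca1 (135920726 to 135940300) lay 4.11 to 6.07 Mb beyond Ptp4a2 on its distal side. Within 10 Mb of Ptp4a2, itself left out, 4 of 224 tested genes were called, against 0 of 12351 elsewhere (two-sided Fisher's exact p = 9.81e-08). Of the next 5 genes by p, none past the threshold, 4 were also on distal chromosome 4. Mecr, a mitochondrial enoyl reductase, had a log2 fold change of 0.61 ± 0.062 (SE), Sytl1 1.12 ± 0.131, Aunip -0.74 ± 0.099 and Fv1, a gene that restricts murine leukaemia virus, 1.72 ± 0.219, with edgeR adjusted p of 0.0667, 0.123, 0.223 and 0.177. The remaining gene was Dhx9, an RNA helicase gene on chromosome 1, at -0.54 ± 0.060 (edgeR adjusted p = 0.107). Outside chromosome 4, 0 of 11804 genes passed in edgeR and 497 had an unadjusted p under 0.05, where no change would give about 590, while 15 were called by DESeq2, 6 by the edgeR likelihood ratio test and 0 by limma-voom.

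**Figure D2:**
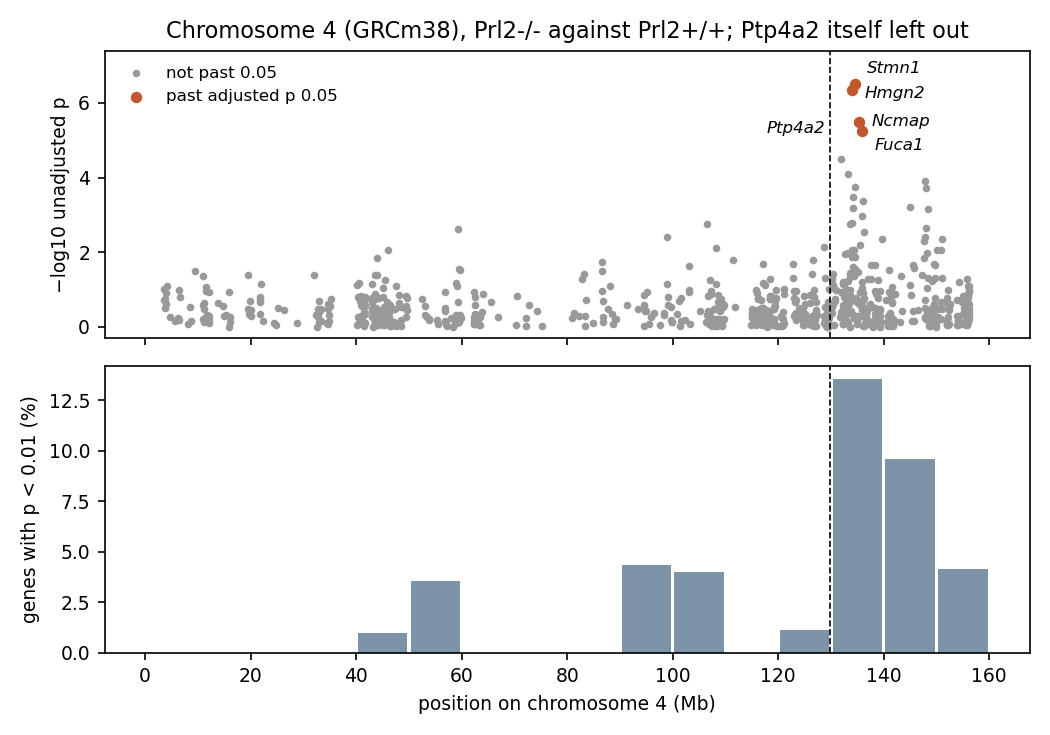
Upper panel, the −log10 of the unadjusted edgeR p of each tested gene on chromosome 4 against its position in Mb, with called genes in orange and Ptp4a2, left out, at the dashed line. Lower panel, the percent of tested genes with an unadjusted p under 0.01 in 10 Mb windows, which was 13.5% from 130 to 140 Mb and 1.11% from 120 to 130 Mb.

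FLT3 and the genes that carry its signal were not detectably different. Flt3 stood at 23.3 ± 4.09 CPM in Prl2+/+ and 28.0 ± 4.80 CPM in Prl2-/- (SD, n = 3 each). Its log2 fold change was 0.26 ± 0.174 (SE), with a 95% confidence interval of -0.152 to 0.678 (edgeR adjusted p = 0.899). Kit, the stem cell factor receptor, was at 0.025 ± 0.106, and Cbl, the ubiquitin ligase that limits both receptors, at 0.0021 ± 0.074 (edgeR adjusted p of 0.965 and 0.996). Of 23 measured genes of FLT3 receptor signalling, 0 passed in edgeR over all genes or adjusted over the list alone; 8 estimates were above 0 and 15 below, and the smallest p was that of Ptpn11, the phosphatase SHP2, at -0.22 ± 0.072 (edgeR adjusted p = 0.899). The list as a whole did not pass (camera adjusted p = 0.30). STAT5 targets (0 of 15 members past the edgeR threshold), ERK feedback genes (0 of 14), FOXO targets (0 of 15), haematopoietic cytokine receptors (0 of 19), immediate early genes (0 of 17) and MYC and ribosome biogenesis genes (0 of 25) did not pass either, with camera adjusted p of 0.739, 0.0856, 0.178, 0.756, 0.756 and 0.152. The intervals leave small differences open, since simulated 1.5-fold changes were recovered in 26% of cases.

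Interferon response genes stood lower on average in the Prl2-/- cells, but not in all libraries. All 21 members had an estimate below 0, with a median log2 fold change of -0.90, among them Ifit1 at -1.19 ± 0.521 (SE), Isg15, Mx1 and Stat2, the last at -0.68 ± 0.197 (edgeR adjusted p = 0.899 for Ifit1 and for Stat2). The list passed in camera (adjusted p = 2.5e-09), with adjusted p = 0.895 with an estimated correlation, and 0 members passed in edgeR over all genes or adjusted over the list alone. The mean log2 CPM was 5.60, 4.74 and 5.39 in Prl2+/+ replicates 1 to 3 and 5.32, 3.31 and 3.91 in Prl2-/- replicates 1 to 3 (exact permutation p = 0.2, n = 3 each). The level of Prl2-/- replicate 1 lay within the Prl2+/+ range. Prl2-/- replicate 2, with the lowest interferon level, had the highest level of erythroid markers, whose mean log2 CPM was 5.05, 5.68 and 4.21 in Prl2+/+ and 4.37, 6.04 and 4.92 in Prl2-/- (exact permutation p = 0.8, n = 3 each). The second principal component, with 12% of the variance, had interferon genes such as Ifi44 and Irf7 at one end and erythroid genes such as Alas2 and Slc4a1 at the other (exact permutation p = 0.2 between genotypes, n = 3 each). Ptp4a2 held rank 1 at the interferon end and Ncmap rank 2 at the erythroid end, so this component also carried genes called between the genotypes. At the preset correlation of 0.01 the camera call held without each of the 6 libraries in turn (camera adjusted p up to 0.000138). The estimated correlation of the members was 0.858, so these leave-outs do not show that the call holds at that correlation.

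Of the 39 lists, 7 passed in camera, 3 higher and 4 lower in Prl2-/-, and 0 passed with an estimated correlation. Ribosomal protein genes had 66 of 74 estimates above 0 and a median of 0.070 (camera adjusted p = 0.00123; adjusted p = 0.92 with an estimated correlation). Only Prl2-/- replicate 1, with a mean log2 CPM of 7.617, lay above the Prl2+/+ range of 7.416 to 7.479. Prl2-/- replicates 2 and 3 lay within it at 7.472 and 7.438 (exact permutation p = 0.5, n = 3 each). Their smallest p belonged to Rps4l, a transcribed processed pseudogene whose counts are uncertain for the same reason as those of Hmgn2, at -0.54 ± 0.113 (SE; edgeR adjusted p = 0.878). Nuclear genes of the respiratory chain had 60 of 79 estimates above 0 and a median of 0.056, with Ndufv1 of complex I at 0.19 ± 0.071 (camera adjusted p = 0.00133 for the list; adjusted p = 0.895 with an estimated correlation). Of this list Prl2-/- replicate 3 lay within the Prl2+/+ range (exact permutation p = 0.2, n = 3 each). Megakaryocyte and platelet markers had 15 of 18 above 0 and a median of 0.27, with the adhesion receptor gene Selp at 1.12 ± 0.340 (camera adjusted p = 0.0189 for the list; adjusted p = 0.909 with an estimated correlation). Their mean log2 CPM was 4.759, 4.201 and 3.957 in Prl2+/+ replicates 1 to 3 and 4.788, 4.620 and 4.364 in Prl2-/- replicates 1 to 3 (exact permutation p = 0.3, n = 3 each). Prl2-/- replicates 2 and 3 thus lay within the Prl2+/+ range. Macrophage markers fell from replicate 1 to 3 in each genotype likewise (4.934, 4.563 and 4.155; 4.782, 4.587 and 4.392). On the lower side were p53 targets, with 13 of 17 below 0 and Plk3 at -0.28 ± 0.092, and cholesterol biosynthesis genes, with 13 of 17 below 0 and a median of -0.11 (camera adjusted p = 0.034 and 0.0377 for the lists; adjusted p = 0.895 for both with an estimated correlation). No member of these 5 lists passed the edgeR threshold over all genes, and no member of the ribosomal, respiratory chain, megakaryocyte or p53 lists passed adjusted over the list alone. The p53 and cholesterol lists were highest in Prl2+/+ replicate 1 and lowest in Prl2-/- replicate 1, as hepatoblast markers were, and with the hepatoblast level as a covariate, chosen after the data were seen, neither passed (camera adjusted p = 0.173 and 0.0941). Prl2-/- replicates 2 and 3 lay within the Prl2+/+ range in both (exact permutation p of 0.5 and 0.3, n = 3 each). Both passed at the preset correlation without the 2 libraries richest in hepatoblast markers (camera adjusted p = 0.00448 and 0.0205), a fit with only 2 libraries per genotype. Each of these 5 lists kept its direction but lost its call without some libraries: Prl2+/+ replicate 3 or Prl2-/- replicate 1 for ribosomal and respiratory chain genes, Prl2+/+ replicate 2 or 3 or Prl2-/- replicate 1 or 2 for megakaryocyte markers, Prl2+/+ replicate 1 or 2 or Prl2-/- replicate 1 or 3 for p53 targets, and Prl2+/+ replicate 2 or Prl2-/- replicate 1 or 3 for cholesterol genes. Without them camera adjusted p reached 0.90 and 0.166 for ribosomal and respiratory chain genes and 0.304, 0.194 and 0.207 for the other 3 lists in that order. Direction and call of the 7 lists were kept under both other scalings.

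Hepatoblast markers varied widely between libraries of the same genotype. These genes, which include Alb, the gene of albumin, and Apoa2, had a mean log2 CPM of 6.13, 3.59 and 0.66 in Prl2+/+ replicates 1 to 3 and -0.99, 5.10 and 1.88 in Prl2-/- replicates 1 to 3 (exact permutation p = 0.6, n = 3 each). Alb had 6264, 1126 and 73 counts in the Prl2+/+ libraries and 42, 3317 and 398 in the Prl2-/- libraries. All 24 measured markers had an estimate below 0, with Apoa2 at -1.39 ± 1.47 (SE; edgeR adjusted p = 0.899), and the list passed in camera as lower (adjusted p = 0.0377; adjusted p = 0.92 with an estimated correlation). The call was lost without Prl2+/+ replicate 1, Prl2+/+ replicate 2, Prl2-/- replicate 1 or Prl2-/- replicate 3 (camera adjusted p up to 0.967), and the direction turned without Prl2-/- replicate 1 (camera adjusted p = 0.917). The mean log2 CPM of B cell markers was 2.72, 2.90 and 4.39 in Prl2+/+ and 4.74, 2.10 and 3.56 in Prl2-/- (exact permutation p = 0.9, n = 3 each). The first principal component, with 69.3% of the variance, had hepatoblast genes such as Apob and Fga at one end and B lineage genes such as Vpreb1 and Cd79a at the other, and its scores did not separate the genotypes (exact permutation p = 0.7, n = 3 each).

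Apart from the megakaryocyte and platelet list, marker lists of the haematopoietic lineages did not pass in the planned camera test. Haematopoietic stem cell markers (24 genes, median log2 fold change 0.12), lymphoid-primed progenitor markers (13 genes, 0.14), granulocyte-monocyte progenitor markers (14 genes, 0.16), B cell markers (10 genes, 0.27) and erythroid markers (21 genes, 0.085) had camera adjusted p of 0.493, 0.515, 0.0603, 0.739 and 0.739. Mpo itself had a log2 fold change of 0.21 ± 0.11 (SE; edgeR adjusted p = 0.899). For haematopoietic transcription factors, mature neutrophil markers, macrophage markers, mast cell, basophil and eosinophil markers, haem biosynthesis genes, T and innate lymphoid markers, endothelial markers and stromal markers, camera adjusted p was 0.739, 0.526, 0.739, 0.0856, 0.756, 0.0603, 0.704 and 0.493. With the hepatoblast level as a covariate, erythroid, haem biosynthesis and T and innate lymphoid lists passed as higher and B cell markers as lower, at camera adjusted p of 0.002, 0.0366, 0.0366 and 0.000253 (adjusted p = 0.808 for each with an estimated correlation). Granulocyte-monocyte progenitor markers passed as higher with limma-voom (camera adjusted p = 0.0183; adjusted p = 0.826 with an estimated correlation). No member of these 13 lists passed the edgeR threshold, over all genes or adjusted over the list alone.

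**Figure D3:**
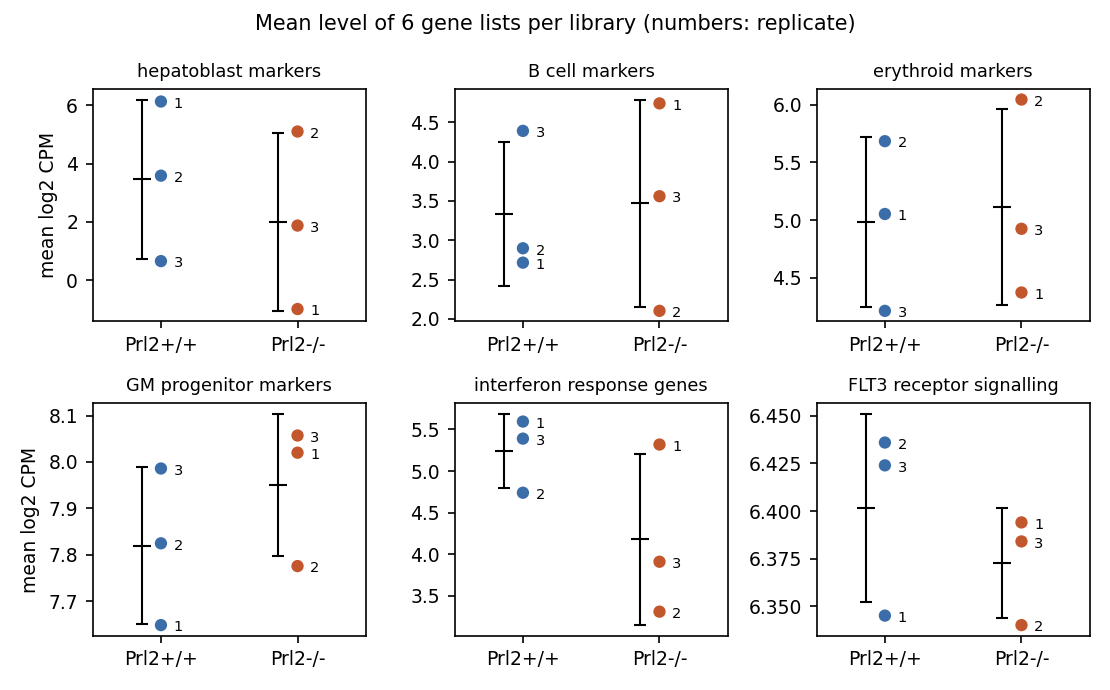
Mean log2 CPM of 6 gene lists, one point per library with its replicate number (blue Prl2+/+, orange Prl2-/-); the black dash and bar give the mean and SD of 3 libraries, and each panel has its own scale. Hepatoblast markers ranged from -0.99 to 6.13 and interferon response genes from 3.31 to 5.60, while FLT3 receptor signalling differed by 0.096 between the highest and lowest library.

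Lists of proliferation and stress genes did not pass the list test either. G1/S genes (22 measured, median log2 fold change 0.010), G2/M genes (22, -0.049) and cell cycle inhibitors (7, -0.14) had camera adjusted p of 0.756, 0.178 and 0.161. Glycolysis, hypoxia, antigen presentation, NF-kB, Notch, amino acid stress, endoplasmic reticulum stress and heat shock lists had camera adjusted p of 0.739, 0.97, 0.509, 0.0856, 0.319, 0.18, 0.661 and 0.756; the NF-kB list passed as lower with the hepatoblast covariate (camera adjusted p = 0.0262; adjusted p = 0.808 with an estimated correlation). Of all their members, Ccl3, a chemokine gene in the NF-kB list, passed adjusted over the list alone, at -0.57 ± 0.093 (SE; edgeR adjusted p over all genes 0.504), and 0 passed over all genes. The PRL phosphatases and partners had a camera adjusted p of 0.263 and were the 1 list that passed with fry, with Ptp4a2 as their single called member among 12. Of the embryonic globins only Hbb-bh1 was measured, at 0.24 (edgeR adjusted p = 0.979), too few for a list test. Median and mean log2 fold change had opposite signs in the STAT5, immediate early, macrophage, G1/S and hypoxia lists, none of which passed.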

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

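The Xist, hepatoblast and B cell covariates, the omission of 1 hepatoblast-rich library per genotype and the omission of genes within 20 Mb of Ptp4a2 were chosen after the data were seen. Against 5 called genes (2 higher, 3 lower), DESeq2 gave 36 (12 and 24) and the likelihood ratio test 21 (9 and 12), each including the 5; limma-voom gave 1 higher gene. With the Xist covariate 3 genes were called and 0 were higher. Without Prl2+/+ replicate 1 and Prl2-/- replicate 2, the libraries richest in hepatoblast markers, 1 gene (Ptp4a2) was called, 0 higher and 1 lower, 0% of genes near Ptp4a2 were called and 11 lists passed against 7; this leaves 2 libraries per genotype. Without genes within 20 Mb of Ptp4a2, 0 genes were called, 0 higher and 0 lower. Leaving out 1 library gave 3 to 4 called genes, 0 to 1 higher, and 1 to 15 lists. With an estimated correlation 0 lists passed, and with fry 1. Apart from the genes left out by construction and the fewer libraries, the cause was not tested. The replicate number as a block gave 1 called gene, 0 higher and 1 lower, and 0% of genes near Ptp4a2. Deviations of same-numbered libraries correlated at -0.638, 0.209 and 0.174, and not every sample correlated best with its own number. A pairing by number was therefore not shown, but correlations over all genes with 3 libraries per genotype cannot exclude it. The other scalings, filters, robust estimation, omitted haemoglobin and ribosomal protein genes, omitted sex-linked genes and the hepatoblast and B cell covariates called the same 5 genes. Some of these settings moved few genes. Without sex-linked genes 12575 of 12576 genes were tested, since Xist alone was measured, and without a filter 12579. Omitting haemoglobin and ribosomal protein genes left 12500. Ptp4a2 stayed past the threshold wherever it was tested. Of 452 other values of named genes, 418 kept their side of the threshold, 21 lost it, 13 gained it and 0 reversed. All 21 losses fell on Fuca1, Ncmap, Hmgn2 and Stmn1, the only genes among them called in the main test. Most of the 452 values belonged to uncalled genes, which had no call to lose, and 14 values of uncalled genes changed sign. The planned Y-linked covariate was not run. Depth limits genes of low abundance, such as Ncmap in Prl2+/+ (0.201 CPM).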

Other observations

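The tests of the flanking sequence and of distance within the region, the Xist, hepatoblast and B cell covariates, and the use of the planned clustering test against a response in trans were chosen after the called genes had been seen, and Ccl6, Ccl9 and Lin28a were named after their values had been seen.

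The chemokine genes Ccl6, Ccl9 and Ccl3 on chromosome 11 had lower levels in all 3 Prl2-/- libraries than in any Prl2+/+ library, though none passed in edgeR; Ccl4, Ccl7 and Ccl12 on the same chromosome overlapped between genotypes. Ccl6 had 304 ± 78.1 CPM in Prl2+/+ and 157 ± 4.71 CPM in Prl2-/- (SD, n = 3 each), a log2 fold change of -0.95 ± 0.172 (SE; edgeR adjusted p = 0.712), Ccl9 -0.61 ± 0.141 (edgeR adjusted p = 0.899) and Ccl3 -0.57 ± 0.0931 (edgeR adjusted p = 0.504). These 3 genes were among the 15 outside chromosome 4 that DESeq2 called, with DESeq2 adjusted p of 2.75e-06, 0.00752 and 0.00529. Lin28a, which encodes an RNA-binding protein of fetal haematopoiesis and lies on chromosome 4 between Hmgn2 and Stmn1, was at 13.9 ± 0.266 CPM in Prl2+/+ and 7.35 ± 1.61 CPM in Prl2-/-, a log2 fold change of -0.92 ± 0.181 (edgeR adjusted p = 0.858; DESeq2 adjusted p = 0.00841).

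Xist, the transcript of the inactive X chromosome, had 239 and 266 counts in Prl2+/+ replicates 1 and 2 and 284 in Prl2-/- replicate 3, and 0 in the other 3 libraries, each of which allows up to 3 counts (0.116, 0.084 and 0.101 CPM for Prl2+/+ replicate 3 and Prl2-/- replicates 1 and 2; counting error only). Of 12576 genes, 11.1% had all 3 Prl2-/- libraries beyond all 3 Prl2+/+ libraries, where chance gives 10%.

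All 5 called genes lay on chromosome 4, from Ptp4a2 to 6.07 Mb beyond it. A response in trans would have no reason to gather there. Fisher's exact test of the gathering gave p = 9.81e-08, which argues against such a response for the 4 neighbours. The median log2 fold change over the 224 genes within 10 Mb was 0.0157 (95% bootstrap interval -0.00487 to 0.05). A bound of 0.2 had been set, so gain or loss of a copy of most of this region is argued against. A copy change of a segment with a minority of these genes need not move the median to that bound, and was not tested. A candidate explanation is sequence of another mouse strain kept around the disrupted gene: among genes that were not called, 22 of 364 within 20 Mb (14 higher, 8 lower) had an unadjusted p under 0.01, against 73 of 12207 elsewhere, a Fisher's exact odds ratio of 10.7 (95% confidence interval 6.24 to 17.7). Called genes included, such genes were 25 of 204 within 20 Mb on the distal side and 1 of 164 on the proximal side, and the odds ratio within 2 Mb against 2 to 20 Mb away was 0.688 (0.0758 to 2.96), too wide to tell a local effect of the disrupted allele. Whether strain sequence may have changed transcription itself or only the alignment of reads stays open, since the strains are not given in the sources used here.

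Few genes outside chromosome 4 passed the threshold: 0 in edgeR, with 497 of 11804 at an unadjusted p under 0.05 where no change would give about 590, 15 in DESeq2 and 6 in the likelihood ratio test. Shares of other cell types that vary between libraries within each genotype could hide changes. With the hepatoblast level as a covariate, however, 0 genes outside chromosome 4 passed and 550 had an unadjusted p under 0.05. That covariate recovered 58% of 2-fold changes in counts simulated without a hepatoblast effect and with the spread of the fit without a covariate. The common biological coefficient of variation was 0.131 in the real hepatoblast fit and 0.264 without a covariate. The simulated rates therefore do not describe the real hepatoblast fit. With the B cell level as a covariate 0 passed as well, but 827 had an unadjusted p under 0.05, above the number without change; 3 of the 10 splits of the libraries, the genotypes among them, gave at least as many in that fit (up to 1281). Embryos of both sexes within each genotype could also hide changes. With the Xist level as a covariate 0 autosomal genes outside chromosome 4 passed, and 3 of the 5 calls were kept. That fit recovered 64% of 2-fold changes in counts simulated with its own spread. Changes of 2-fold or less therefore stay open. Simulated 1.5-fold changes were recovered in 18% of cases with Xist and 26% without a covariate. The rate was 16% with the hepatoblast covariate, again in counts simulated without its effect or its spread. Without a covariate 68% of 2-fold and 94% of 4-fold changes were recovered, so some larger changes could be missed too. Genes under a mean CPM of 4 were not among those changed, and the B cell fit was not simulated.

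The genotypes gave 5 called genes and the highest of the other splits of the 6 libraries gave 2, so 1 of 10 splits gave as many. With 10 splits the share cannot fall under 0.1, so the splits are too few for a share under 0.05.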
